A study of Arabidopsis thaliana with 8 samples.

How the data were processed

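RNA-seq of shoot and root tissue of Arabidopsis Col-0 was analysed, with 4 samples of each tissue grouped by the tissue named in the labels. Per the labels' protocols, polyadenylated RNA was selected with poly-T beads and cDNA was made with random hexamers, by steps that do not mark strand. Fragments of 370 to 420 bp were selected, and pairs of 150 bp reads were taken on a NovaSeq instrument. The growth protocol attached to these samples describes another species, so it was not used, and the age, medium and harvest of these plants are not given in the sources used here. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the TAIR10 genome build were used. The strand setting, the treatment of reads shared between genes or copies, and the annotation release are not given in the sources used here.

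The deposited table is named as counts, but its values are FPKM made by the authors, relative to the table's gene length and to a scaled library size whose scaling method is not given. This was worked out from the values, which are not whole, whereas each value times the gene length is a whole multiple of 1 step per library (largest deviation 1.37e-09 reads), so the whole reads were recovered. The scaled library sizes were 0.770 to 0.865 times the read total in shoot and 1.18 to 1.25 times in root. The table holds 33199 genes, 32833 of them annotated and 366 unannotated models, and gives 23 gene symbols as dates, SEP3 among them, so genes were matched by identifier. Of the 422 members of the 21 gene lists, 417 had their symbol in the table or in the reference's gene names, and 367 were tested. Symbols in the text are common ones, and the table lists LHCB1.2 as LHCB1.1, LHCB1.4 as LHB1B1, GC1 as GASA9, CER6 as CUT1, CER4 as FAR3, FIL as YAB1, PHB as ATHB-14, NRT1.5 as NPF7.3, NRT1.7 as NPF2.13, AHA2 as HA2 and PRR7 as APRR7.

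The comparison, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined, on the assumption that the table held counts. Since it holds FPKM, the test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with a trend in the prior variance, and no count model was used. The pseudocount of 0.5 and the filter of at least 0.5 FPKM in at least 4 of the 8 libraries were chosen once the unit was known. P-values were adjusted by Benjamini and Hochberg's method over the 20314 genes tested, 149 of them unannotated models, and an adjusted p under 0.05 was called a change. Fold changes are on the log2(FPKM + 0.5) scale. Where a tissue had 0 reads, the fold is a lower bound against 3 reads over its 4 libraries, and where it had 1 to 3 reads, the ratio is given with its 95% counting interval. Such bounds and intervals, and the exact binomial intervals of shares, cover counting error only. At 1 kb of gene length, 3 reads in 1 library correspond to 0.192 to 0.375 FPKM.

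Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 21 lists, beside camera with an estimated correlation and fry. Families of 10 or more tested genes were taken from the table's family column, which holds protein domain names, and tested in the same way. The named genes are the 6 highest and 6 lowest log2 fold changes among called genes with a mean of at least 20 CPM and no overlap of the tissues in CPM. Added to them, from each list, are the most abundant tested member, the called member with the largest change and the called member with the largest change against the list's majority. That gave 54 genes. Library totals, genes with a read, the share of the 10 most abundant genes and the shares of plastid and mitochondrial genes were compared by exact two-sided permutation tests, for which 4 against 4 libraries give no p under 0.0286. Genes were called detected in 1 tissue with at least 1 CPM in each of its libraries and under 0.1 CPM in each of the other's.

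Replicates of a tissue differed by more than sampling noise (chi-square per gene 7.47 to 22.6 over the pairs), so none was counted as a copy of another. The test was checked on simulated reads for 20289 genes with the samples' library sizes and 1 mean per gene shared by both tissues. It recovered 62 of 100 genes changed 2-fold and 85 of 100 changed 4-fold, with 10 unchanged genes called (6.37% of calls). Only 200 genes were changed there, against most genes in the data, so these shares do not carry over to the comparison of tissues. In that simulation a raised list of 30 genes passed and 0 of 20 unchanged lists did. Genes were drawn independently of each other there, so this cannot check the preset correlation, while the estimates for the real lists reached 0.849. Alternatives were other scalings of the recovered reads (median of ratios, library totals alone, and trimmed means without organelle genes and the 100 most abundant genes), limma-voom on the recovered reads, other filters, the replicate number as a block, and leaving out each library. Pseudocounts of 0.1 and 1, leaving out root libraries 1 and 2, applying the filter again after leaving out a library, the organelle shares without rRNA genes, and the families under the choices made for the gene counts were added after the data were seen. For overlaps between genes, the exons of each gene in the RefSeq annotation of the reference genome were compared by identifier with those of all other genes, and no coordinates of that annotation are given.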

Results

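Messenger RNA was sequenced from shoots and roots of Arabidopsis Col-0, with 4 samples of each tissue, and FPKM values were given for 33199 genes, of which 366 were unannotated models. The reads assigned to genes numbered 10044638, 10388042, 11662309 and 10310487 in shoot libraries 1 to 4, and 12460762, 9857791, 11791553 and 10280706 in root libraries 1 to 4. The mean totals of 10601369 ± 722418 in shoot and 11097703 ± 1230748 in root (SD, n = 4) were not shown to differ by an exact two-sided permutation test (p = 0.571, adjusted p = 0.571). After a filter on low values, 20314 genes were tested, which held 99.9% of the reads. The labels do not say that the 4 samples of a tissue came from separate cultures, so each p-value measures only the spread between these samples, which may be technical. Means are given ± SD over 4 libraries per tissue, log2 fold changes are root minus shoot on the scale of log2(FPKM + 0.5), which understates the change of low genes, and adjusted p-values of single genes are from limma.

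The comparison of root with shoot asked which genes differ in level between the 2 tissues. Of the 12 genes named by size of change, the 6 higher in shoot encode light-harvesting proteins, Rubisco small subunits and a carbonic anhydrase of the chloroplast, and the 6 higher in root include peroxidase, lectin and beta-glucosidase genes. LHCB1.1 (AT1G29920, chromosome 1, 10474656 to 10475969 in TAIR10), which encodes a chlorophyll-binding protein of light-harvesting complex II, stood at 8763 ± 1127 FPKM in shoot and 2.19 ± 2.25 in root (log2 fold change -12.04, SE 0.47, adjusted p = 3.38e-09). BGLU21 (AT1G66270, chromosome 1, 24699868 to 24703166), a beta-glucosidase gene, had 0 reads in the 4 shoot libraries and 289.7 ± 20 FPKM in root, at least 6716-fold higher when set against 3 reads over the 4 shoot libraries. Of the 20314 genes tested, 14130 (69.6%) changed, 7630 of them higher in root and 6500 higher in shoot. A change of at least 2-fold was called for 7920 genes, 4250 higher in root and 3670 higher in shoot, and changes of 16-fold or more for 617 and 635. With 1 root library left out and the filter applied again, which by construction drops genes found in root alone, 2853 to 2992 genes were at least 2-fold higher in root and 3668 to 3700 in shoot (43.7% to 44.7% higher in root). Of all changed genes, 48.5% to 48.8% were then higher in root. With any 1 shoot library left out instead, where the filter drops genes found in shoot alone, 56.9% were. Overlap was judged in CPM, relative to library totals and not to the scaled library sizes. The values of the 4 root and the 4 shoot libraries did not overlap for 14981 genes (73.7%), against 2.86% by chance. With library totals alone as the scaling, 12142 genes were higher in root and 3997 in shoot, and the median log2 fold change of all tested genes moved from 0.07 to 0.58.

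LHCB1.4 stood at 2679 ± 1118 FPKM in shoot and 0.274 ± 0.168 in root (log2 fold change -11.7, SE 0.26, adjusted p = 1.28e-10). LHCB1.2 stood at 7260.2 ± 1549.6 and 5.34 ± 5.67 FPKM (log2 fold change -11.04, SE 0.74, adjusted p = 2.16e-07). RBCS2B and RBCS3B, which encode Rubisco small subunits, had log2 fold changes of -10.72 (SE 1.0) and -10.44 (SE 0.95). BCA1, a chloroplast carbonic anhydrase gene, stood at 1766 ± 308 FPKM in shoot and 1.05 ± 1.49 in root (log2 fold change -10.62, SE 0.53, adjusted p = 1.91e-08), with 3.19 FPKM in root library 1 and 0.0252 to 0.954 in the other root libraries. Leaving out root library 1 moved the log2 fold changes of LHCB1.2, RBCS2B and RBCS3B to -11.67, -11.71 and -11.37, and leaving out root library 3 moved them to -10.38, -9.85 and -9.62. The LHCB1 genes and the RBCS genes are near-identical copies, so how reads were split between copies is uncertain. In root, PER27, a class III peroxidase gene, had 289.7 ± 55.8 FPKM and 0 reads in shoot (at least 4588-fold higher). JAL10, a jacalin-related lectin gene, had 163 ± 31 FPKM and 0 reads in shoot (at least 2789-fold higher). PER45, another peroxidase gene, stood at 0.953 ± 0.913 FPKM in shoot and 408 ± 73.1 in root (log2 fold change 8.36, SE 0.40, adjusted p = 1.46e-08). MLP329, a gene of the major latex protein family, stood at 1.91 ± 1.66 FPKM in shoot and 650.3 ± 115 in root (log2 fold change 8.44, SE 0.53, adjusted p = 1.24e-07, or 7.81 without shoot library 2). AT4G15390, listed as an HSR201-like protein, stood at 0.13 ± 0.109 and 225 ± 49.3 FPKM (log2 fold change 8.48, SE 0.18, adjusted p = 1.17e-10).

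All of the photosynthesis genes tested were higher in shoot. This held for 39 of 39 genes of light harvesting and the photosystems (median log2 fold change -7.58, camera adjusted p = 3.2e-19, but adjusted p = 0.179 with an estimated correlation). It held for 26 of 26 genes of the Calvin cycle and photorespiration (median -7.64, camera adjusted p = 2.83e-13, but adjusted p = 0.173 with an estimated correlation). LHCB1.3, the most abundant gene of the first list, stood at 20791 ± 3765 FPKM in shoot and 63.1 ± 52.1 in root (log2 fold change -8.83, SE 0.58, adjusted p = 1.88e-07). RBCS1A stood at 20718 ± 1708 FPKM in shoot and 54.6 ± 54.3 in root (log2 fold change -9.23, SE 0.67, adjusted p = 3.83e-07), or a log2 fold change of -9.86 without root library 1. All 15 tested genes of chlorophyll synthesis were higher in shoot (median -4.36, camera adjusted p = 5.82e-10, but adjusted p = 0.119 with an estimated correlation). Among them CHLH, a subunit of magnesium chelatase, stood at 681 ± 66.1 and 7.55 ± 3.4 FPKM in shoot and root (log2 fold change -6.51, SE 0.27, adjusted p = 4.45e-09). CRD1, a subunit of the cyclase that forms protochlorophyllide, stood at 1527 ± 232 and 14.9 ± 2.68 FPKM (log2 fold change -6.63, SE 0.15, adjusted p = 1.24e-10). Of 13 starch genes, 12 were higher in shoot (median -2.59, camera adjusted p = 7.65e-06, but adjusted p = 0.163 with an estimated correlation). ISA3 did not pass (log2 fold change -0.01, adjusted p = 0.977), and with library totals alone it was at 0.52 (adjusted p = 0.0242). APS1, the small subunit of ADP-glucose pyrophosphorylase, stood at 249.6 ± 30.5 FPKM in shoot and 19.7 ± 0.237 in root (log2 fold change -3.62, SE 0.10, adjusted p = 2.83e-10). GBSS1, the granule-bound starch synthase, stood at 30.4 ± 6.0 and 0.599 ± 0.384 FPKM (log2 fold change -4.85, SE 0.22, adjusted p = 1.1e-08). Root libraries 1 and 2 held more photosynthesis transcripts than root libraries 3 and 4: the 65 photosynthesis genes lay at a median 0.827%, 0.629%, 0.253% and 0.346% of their shoot level in root libraries 1 to 4. GBSS1 was at 1.17 FPKM in root library 1 and at 0.360 to 0.461 in the others, while APS1 was at 19.4 to 20 in all 4.

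Of the 21 lists fixed beforehand, 15 passed camera with its preset correlation, 8 of them higher in root and 7 higher in shoot. With an estimated correlation none passed after adjustment, while 8 had an unadjusted p under 0.05. The correlation is not all that differs between these 2 settings of camera. Leaf patterning had an estimate of 0.00796, under the preset 0.01, and its camera adjusted p still went from 2.75e-04 to 0.0597. The loss of calls therefore does not by itself show that correlated genes made these lists pass. By fry, which tests whether a list's genes move on balance in 1 direction and does not compare them with the other genes, 19 passed. Since 69.6% of all tested genes changed, a pass by fry does not set a list apart from genes in general.

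**Figure D1:**
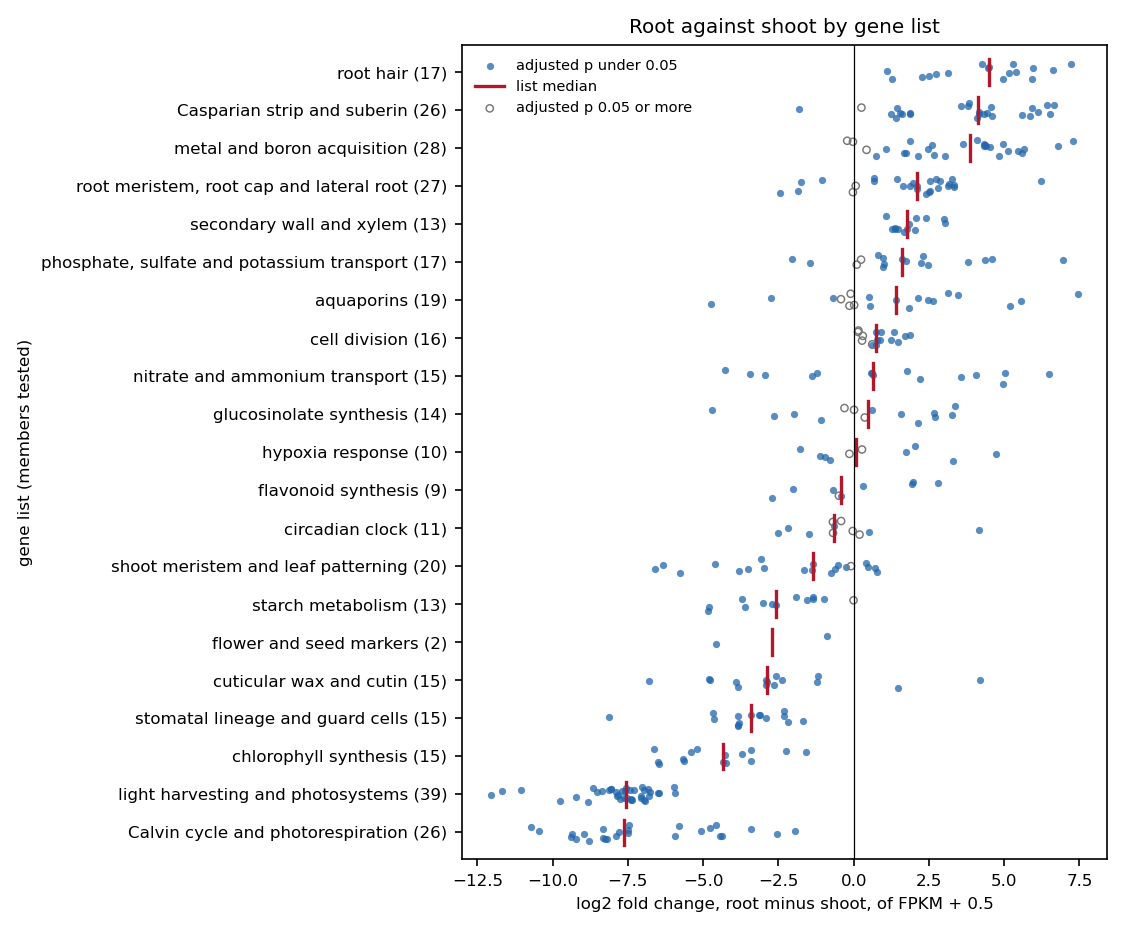
Log2 fold change (root minus shoot, of FPKM + 0.5) of each tested member of 21 gene lists, with the number tested in brackets, filled points for an adjusted p under 0.05, open points for the rest and a red bar at the list median. Medians run from -7.64 for the Calvin cycle and photorespiration to 4.48 for root hair genes. Called members lie on both sides of 0 in the glucosinolate, flavonoid, hypoxia and clock lists, and also in other lists, such as wax and cutin, leaf patterning, root meristem, nitrate and ammonium, and aquaporins.

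Stomatal genes and most genes of the cuticle and of leaf patterning were higher in shoot. All 15 genes of the stomatal lineage and guard cells were higher in shoot (median -3.4, or -3.86 with genes at 0 reads in a tissue set at their bound, camera adjusted p = 2.89e-08, but adjusted p = 0.0597 with an estimated correlation). GC1, a gibberellin-regulated gene active in guard cells, stood at 209.7 ± 61.6 FPKM in shoot and 0.342 ± 0.612 in root (log2 fold change -8.14, SE 0.38, adjusted p = 1.16e-08). It was at 1.26 FPKM in root library 1 and at most 0.110 in the other root libraries. Of 15 wax and cutin genes, 13 were higher in shoot and 2 in root (median -2.88, camera adjusted p = 4.27e-05, but adjusted p = 0.119 with an estimated correlation). CER6, an enzyme that elongates fatty acids for wax, stood at 272 ± 34.5 FPKM in shoot and 2.05 ± 0.862 in root (log2 fold change -6.79, SE 0.21, adjusted p = 7.11e-10). The exceptions were CER4, a fatty acyl-CoA reductase gene with 2 shoot reads and 9.55 ± 3.02 FPKM in root (a ratio of 317 with a 95% counting interval of 87.7 to 2616), and GPAT6, an acyltransferase gene of cutin synthesis (log2 fold change 1.48). GPAT6 and the other members outside the naming rule, in this list and the others, were named after their values were seen. Of 20 genes of the shoot meristem and leaf patterning, 15 were higher in shoot, 4 were higher in root and ANT did not pass (median -1.36, camera adjusted p = 2.75e-04, but adjusted p = 0.0597 with an estimated correlation). FIL, a regulator of the abaxial leaf side, had 48.1 ± 5.66 FPKM in shoot and 0 reads in root (at least 1058-fold higher in shoot). REV was higher in root (6.93 ± 0.849 and 12.1 ± 2.01 FPKM in shoot and root, log2 fold change 0.76, SE 0.15, adjusted p = 8.2e-04), as was PHB (11 ± 1.04 and 15 ± 1.85 FPKM, log2 fold change 0.42, SE 0.12, adjusted p = 0.00853). The others were KNAT1 (0.49) and KAN2 (0.70). REV and PHB encode class III homeodomain leucine zipper proteins, which also pattern vascular tissue. Without root libraries 1 and 2, PHB was no longer called (0.31, adjusted p = 0.0929). With library totals alone KAN1, called higher in shoot at -0.27, was at 0.25 (adjusted p = 0.061). KNAT2, AS2 and PHV, counted as higher in shoot, also lost their call (-0.36, adjusted p = 0.135, -0.21, adjusted p = 0.342 and -0.24, adjusted p = 0.156).

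Most genes of root hairs, the endodermal barrier and the root apex were higher in root. All 17 tested root hair genes were higher in root (median 4.48, or 7.22 with genes at 0 shoot reads at their bound, camera adjusted p = 1.64e-08, but adjusted p = 0.119 with an estimated correlation). PRP3, a proline-rich wall protein gene, had 2 shoot reads and 84.2 ± 26.7 FPKM in root, a ratio of 1756 with a 95% counting interval of 486 to 14502. CSLD3, a cellulose synthase-like gene needed for hair growth, stood at 11.2 ± 1.32 and 24.6 ± 3.52 FPKM in shoot and root (log2 fold change 1.1, SE 0.13, adjusted p = 1.61e-05). Of 26 genes of the Casparian strip and suberin, 24 were higher in root (median 4.13, or 4.17 with bounds, camera adjusted p = 6.85e-09, but adjusted p = 0.119 with an estimated correlation). CASP1, a membrane protein of the Casparian strip domain, stood at 1.61 ± 0.702 FPKM in shoot and 176 ± 41.5 in root (log2 fold change 6.42, SE 0.24, adjusted p = 2.24e-09). PER64, a peroxidase gene of Casparian strip lignin, stood at 0.397 ± 0.267 and 87.7 ± 15.7 FPKM (log2 fold change 6.65, SE 0.22, adjusted p = 9.89e-10). FAR1, a reductase that makes fatty alcohols found in suberin, was higher in shoot (34.6 ± 9.02 and 9.29 ± 2.14 FPKM, log2 fold change -1.82, SE 0.21, adjusted p = 1.95e-05). SCR did not pass (0.26, adjusted p = 0.0889), but was called higher in root with library totals alone (0.79, adjusted p = 5.69e-04). Of 27 genes of the root meristem, root cap and lateral roots, 21 were higher in root and 4 in shoot (median 2.1, or 2.53 with bounds, camera adjusted p = 2.75e-04, but adjusted p = 0.119 with an estimated correlation). PIN2, an auxin efflux carrier of the root tip, stood at 0.175 ± 0.161 FPKM in shoot and 48.6 ± 3.53 in root (log2 fold change 6.21, SE 0.17, adjusted p = 3.74e-10). The root apex regulators PLT1, PLT2, WOX5 and SMB had 4.63 ± 0.674, 3.16 ± 0.59, 2.46 ± 0.627 and 4.01 ± 0.858 FPKM in root and 0, 0, 7 and 0 reads over the 4 shoot libraries. The genes higher in shoot were the auxin efflux carriers PIN4 (41.7 ± 7.41 and 7.2 ± 0.918 FPKM, log2 fold change -2.44, SE 0.14, adjusted p = 4.63e-08), PIN7 (-1.86) and PIN3 (-1.74), and BRX (-1.06). AUX1, an auxin influx carrier, stood at 46.5 ± 5.78 and 48.4 ± 3.48 FPKM (log2 fold change 0.06, SE 0.10, adjusted p = 0.599) and ARF7 at a log2 fold change of -0.03. With library totals alone AUX1 passed at 0.61 (adjusted p = 9.82e-05) and ARF7 at 0.51 (adjusted p = 0.0231). With 1 root library left out and the filter applied again to the libraries left, which drops genes found in root alone, the list's median was 0.33 to 0.39 and it did not pass (adjusted p = 0.412 to 0.594).

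Transporters of mineral nutrients were mostly higher in root, with members on both sides. Of 28 genes of metal and boron acquisition, 25 were higher in root and none in shoot, with HMA2, ZIP1 and ZIP5 not passing (median 3.86, camera adjusted p = 1.02e-08, but adjusted p = 0.0597 with an estimated correlation). ZIP1 passed with library totals alone (0.86, adjusted p = 0.00388). AHA2, a proton pump of the plasma membrane, stood at 105 ± 18.8 FPKM in shoot and 351 ± 36.5 in root (log2 fold change 1.75, SE 0.14, adjusted p = 1.0e-06). F6'H1, an enzyme of coumarin synthesis, stood at 0.233 ± 0.233 and 110.1 ± 8.95 FPKM (log2 fold change 7.29, SE 0.20, adjusted p = 3.52e-10). Of 17 phosphate, sulfate and potassium transporters, 13 were higher in root, 2 in shoot, and SULTR2;2 and SULTR3;5 did not pass (median 1.59, camera adjusted p = 0.00161, but adjusted p = 0.179 with an estimated correlation). With library totals alone SULTR2;2 (0.59, adjusted p = 0.00943) and SULTR3;5 (0.76, adjusted p = 0.00301) were higher in root. The phosphate transporter gene PHT1;1, which has near-identical copies, stood at 1.81 ± 0.584 FPKM in shoot and 279.8 ± 15.4 in root (log2 fold change 6.97, SE 0.18, adjusted p = 2.63e-10). The 2 higher in shoot were the sulfate transporter gene SULTR2;1 (44.6 ± 7.37 and 10.3 ± 2.08 FPKM, log2 fold change -2.06, SE 0.16, adjusted p = 7.93e-07) and the potassium channel gene AKT2 (log2 fold change -1.47). Of 15 nitrate and ammonium transporters, 10 were higher in root and 5 in shoot, and the list did not pass (median 0.63, camera adjusted p = 0.265). NRT1.5, which loads nitrate into the xylem, stood at 2.79 ± 1.91 FPKM in shoot and 266 ± 29.2 in root (log2 fold change 6.5, SE 0.32, adjusted p = 1.62e-08). NRT1.7, which loads nitrate into the phloem of source leaves, stood at 49.4 ± 12 and 2.09 ± 0.639 FPKM (log2 fold change -4.28, SE 0.21, adjusted p = 2.01e-08). The other transporters higher in shoot were NRT2.7 (-3.43), NRT1.11 (-2.93), AMT2 (-1.39) and NRT1.8 (-1.21).

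**Figure D2:**
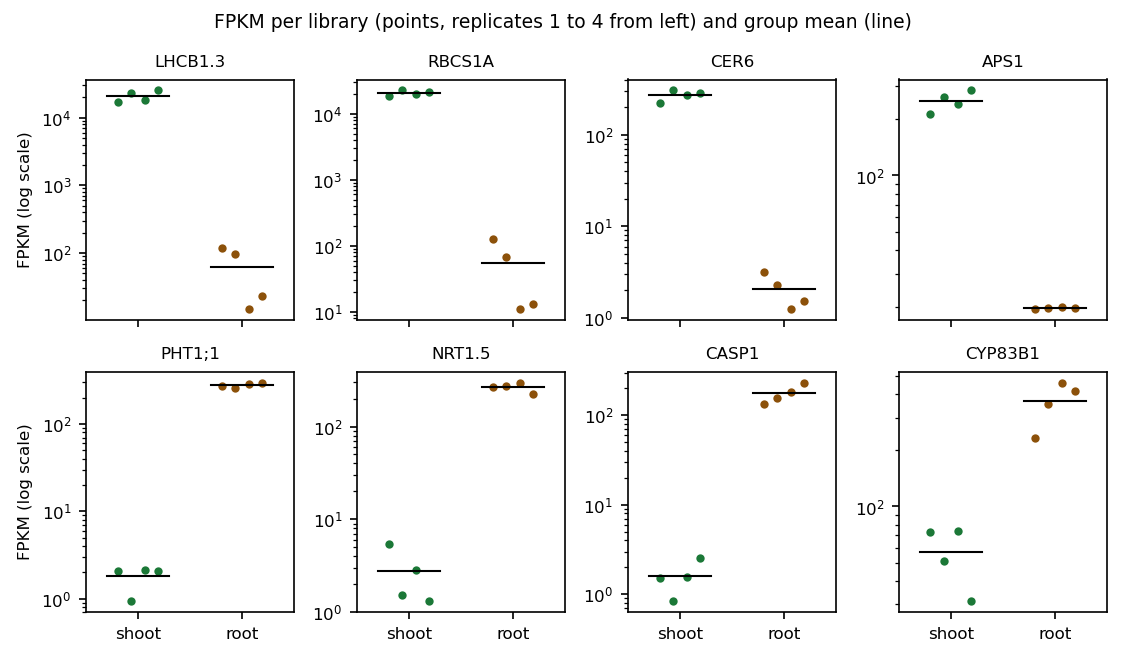
FPKM on a log axis in each of the 4 shoot and 4 root libraries (points, replicates 1 to 4 from left) with the mean of each tissue (line) for 8 named genes. LHCB1.3, RBCS1A, CER6 and APS1 were higher in every shoot library than in any root library, PHT1;1, NRT1.5, CASP1 and CYP83B1 were higher in every root library, and LHCB1.3 stood at 119 and 95.8 FPKM in root libraries 1 and 2 and at 14.8 and 22.9 in 3 and 4.

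Of 19 aquaporin genes, 12 were higher in root, 3 were higher in shoot and 4 did not pass (median 1.4, camera adjusted p = 0.020, but adjusted p = 0.39 with an estimated correlation and adjusted p = 0.0649 with library totals alone). TIP2;3, a tonoplast aquaporin gene, had 91.4 ± 33.4 FPKM in root and 0 reads in shoot (at least 1246-fold higher in root). PIP2;6, an aquaporin gene of the plasma membrane, stood at 178 ± 23.1 FPKM in shoot and 6.29 ± 1.61 in root (log2 fold change -4.74, SE 0.17, adjusted p = 1.68e-09). The others higher in shoot were TIP2;1 (-2.74) and PIP1;4 (-0.70), which lost its call with library totals alone (-0.16, adjusted p = 0.307). TIP1;2, the most abundant member, stood at 1119 ± 190.4 FPKM in shoot and 1020.4 ± 235 in root (log2 fold change -0.14, SE 0.19, adjusted p = 0.521). It was at 1372 FPKM in root library 4 and 891 to 911 in the other root libraries. With library totals alone TIP1;2 was higher in root (0.41, adjusted p = 0.0272), as was PIP2;7 (0.45, adjusted p = 0.0184), which stood at -0.10 otherwise. PIP2;5 and PIP2;8 were the other members that did not pass.

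Most genes of the secondary wall and of cell division were higher in root. All 13 tested genes of the secondary wall and xylem were higher in root (median 1.79, camera adjusted p = 2.66e-05, but adjusted p = 0.173 with an estimated correlation). LAC11, a laccase gene of lignin synthesis, stood at 2.86 ± 1.08 FPKM in shoot and 26.3 ± 2.91 in root (log2 fold change 3.05, SE 0.21, adjusted p = 2.94e-07). XCP2, a cysteine protease gene of xylem vessels, stood at 33.8 ± 3.87 and 81.9 ± 9.86 FPKM (log2 fold change 1.26, SE 0.11, adjusted p = 2.27e-06). Of 16 cell division genes, 11 were higher in root and none in shoot, or 12 and none when adjusted over the list alone (median 0.75, camera adjusted p = 0.00781, but adjusted p = 0.456 with an estimated correlation). CDKB1;1, a mitotic cyclin-dependent kinase gene, stood at 3.06 ± 0.475 FPKM in shoot and 12.6 ± 0.991 in root (log2 fold change 1.88, SE 0.13, adjusted p = 2.48e-07). TSO2, a ribonucleotide reductase subunit gene, stood at 16.9 ± 2.79 and 31.3 ± 6.8 FPKM (log2 fold change 0.86, SE 0.16, adjusted p = 7.99e-04). The 5 that did not pass over all genes were CYCB1;2, CYCA1;1, KNOLLE, HINKEL and AUR1. These 5 were called higher in root with library totals alone, at 0.84, 0.78, 0.68, 0.67 and 1.14 (adjusted p = 0.00121, 0.0156, 0.0274, 0.0183 and 0.0019).

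Genes of glucosinolate and flavonoid synthesis, low oxygen and the clock went both ways, and none of these 4 lists passed camera. Of 14 glucosinolate genes, 7 were higher in root and 4 in shoot (median 0.48, camera adjusted p = 0.564). The indolic genes CYP83B1 (57.3 ± 20.5 and 367 ± 99.3 FPKM in shoot and root, log2 fold change 2.7, SE 0.29, adjusted p = 9.69e-06), CYP79B2 (3.37), CYP79B3 (2.14) and MYB34 (3.28) were higher in root. The aliphatic genes CYP79F1 (19.6 ± 4.29 and 0.298 ± 0.333 FPKM, log2 fold change -4.72, SE 0.30, adjusted p = 1.19e-07), MAM1 (-1.97), CYP83A1 (-1.08) and MYB29 (-2.66) were higher in shoot. CYP79F2, of the aliphatic branch too, was higher in root (6.99 ± 3.52 and 21.4 ± 9.87 FPKM, log2 fold change 1.57, SE 0.38, adjusted p = 0.00341), as were the indolic regulator MYB122 (2.68) and SUR1 (0.59), and whether the branches differ was not tested. MYB28, BCAT4 and MYB51 did not pass, but MYB28 was higher in root with library totals alone (0.90, adjusted p = 0.00166). Of 9 tested flavonoid genes, 4 were higher in root and 4 in shoot, or 4 and 5 when adjusted over the list alone (camera adjusted p = 0.896). The list's median was -0.44 but its mean was 0.07, and its median was 0.11 with library totals alone. CHS, the chalcone synthase gene, stood at 38 ± 9.4 FPKM in shoot and 148 ± 13.4 in root (log2 fold change 1.97, SE 0.17, adjusted p = 1.54e-06). MYB12, a regulator of flavonol synthesis, stood at 0.0767 ± 0.0645 and 3.57 ± 0.641 FPKM (log2 fold change 2.81, SE 0.17, adjusted p = 1.02e-07). FLS1 (1.94) and UGT78D2 (0.30) were also higher in root. DFR (-2.73) and LDOX (-2.01), of the anthocyanin branch, were higher in shoot with F3'H (-0.69) and CHI (-0.44). Both F3'H (-0.31, adjusted p = 0.0925) and CHI (0.11, adjusted p = 0.487) lost their calls with library totals alone. UGT78D1 did not pass. Apart from this list and cell division, the counts adjusted over the list alone were those given over all genes.

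Of 10 genes of the response to low oxygen, 4 were higher in root and 4 in shoot (median 0.07, camera adjusted p = 0.649). ADH1, the alcohol dehydrogenase gene, stood at 29.8 ± 12.7 FPKM in shoot and 103 ± 47.5 in root (log2 fold change 1.73, SE 0.43, adjusted p = 0.00433). SUS4, a sucrose synthase gene, stood at 0.205 ± 0.118 and 19.8 ± 9.65 FPKM (log2 fold change 4.74, SE 0.30, adjusted p = 1.46e-07). PDC1 (3.29) and HRE1 (2.05) were also higher in root. SAD6 (-1.78), PCO2 (-1.13), HRE2 (-0.96) and HB1 (-0.79) were higher in shoot, and LBD41 and PCO1 did not pass. Of these, PCO2 (-0.62, adjusted p = 0.0556), HRE2 (-0.66, adjusted p = 0.0653) and HB1 (-0.24, adjusted p = 0.326) lost their calls with library totals alone. Of 11 clock genes, 2 were higher in root and 4 in shoot (median -0.66, camera adjusted p = 0.438). PRR7, a pseudo-response regulator, stood at 78.6 ± 8.61 FPKM in shoot and 17.4 ± 4.61 in root (log2 fold change -2.17, SE 0.17, adjusted p = 7.62e-07). CCA1 (-2.51), LHY (-1.47) and LUX (-0.66) were also higher in shoot, but LHY (-0.98, adjusted p = 0.0695) and LUX (-0.14, adjusted p = 0.532) were not called with library totals alone. ELF4, of the evening complex, stood at 1.4 ± 0.65 FPKM in shoot and 36.1 ± 17.5 in root (log2 fold change 4.17, SE 0.37, adjusted p = 1.94e-06), and TOC1 was at 0.52. GI, PRR5, PRR9, ELF3 and RVE8 did not pass, and with library totals alone GI (0.51, adjusted p = 0.010) and ELF3 (0.73, adjusted p = 3.46e-04) were higher in root. Only 2 of 15 flower and seed markers had values high enough to be tested, and both were higher in shoot, while the list did not pass (camera adjusted p = 0.135). SEP3, a MADS-box gene of floral organs, stood at 13.8 ± 2.76 FPKM in shoot and 0.113 ± 0.226 in root (log2 fold change -4.58, SE 0.24, adjusted p = 2.77e-08). SEP3 was at 0.453 FPKM in root library 1 and 0 in the others. PI had a log2 fold change of -0.88 and lost its call with library totals alone (-0.51, adjusted p = 0.137).

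Of 186 protein domain families with 10 or more tested genes, 10 passed camera. With an estimated correlation none did (adjusted p = 0.916 to 0.983 for these 10), while 6 had an unadjusted p under 0.05. TCP lost its call at an estimate of -0.0375, under the preset 0.01, so a high correlation between its genes was not what ended that call. With any 1 root library left out and the filter applied again, which by construction drops genes found in root alone, 6 families passed. Higher in root were SCP (9 of 11 higher in root and 1 in shoot, median 4.37), Cu_bind_like (16 of 22 higher in root and 3 in shoot, median 2.03) and DUF6 (27 of 39 higher in root and 7 in shoot, median 1.41). So were Peptidase_C1 (19 of 23 higher in root and 4 in shoot, median 1.27) and NAM (43 of 71 higher in root and 11 in shoot, median 0.84). Higher in shoot were CCT (2 of 23 higher in root and 15 in shoot, median -1.81), ABC1 (2 of 16 higher in root and 11 in shoot, median -1.55) and TCP (0 of 17 higher in root and 12 in shoot, median -1.34). So were AA_kinase (1 of 12 higher in root and 9 in shoot, median -0.74) and Radical_SAM (0 of 12 higher in root and 9 in shoot, median -0.43). CCT, TCP and ABC1 still passed with library totals alone. The other 7, all 5 higher in root among them, did not (adjusted p = 0.080 to 0.121), and the median of Radical_SAM was 0.11, while the other 9 medians kept their sign. TCP and NAM are plant transcription factor domains, and Peptidase_C1 is the papain-like cysteine protease domain. Genes with at least 1 CPM in every root library and under 0.1 CPM in every shoot library numbered 600, and the reverse held for 121 genes. CPM are relative to library totals, a scale on which genes lie further towards root than in the FPKM values. A single library can also decide a gene: SEP3, with 620 shoot reads and 9 root reads, all in root library 1, was not counted. At limits of 2 and 0.05 CPM these counts were 299 and 57.

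Expression was more concentrated in shoot. The 10 most abundant genes held 10.9% ± 0.836 of shoot reads and 3.75% ± 0.283 of root reads (SD, n = 4, exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries can give, adjusted p = 0.0357). The nuclear photosynthesis genes of both lists held 21.4%, 25.1%, 21.8% and 25.2% of reads in shoot libraries 1 to 4 and 0.405%, 0.312%, 0.213% and 0.221% in root libraries 1 to 4. At least 1 read was found for 21144 ± 382 genes in shoot and 22575 ± 253 in root (n = 4, exact permutation p = 0.0286, adjusted p = 0.0357). Plastid genes held 0.0340% ± 0.00667 of shoot reads and 0.00252% ± 0.000149 of root reads, and mitochondrial genes 0.00753% ± 0.00117 and 0.0446% ± 0.0101 (n = 4, exact permutation p = 0.0286 and adjusted p = 0.0357 for each). Genes of rRNA held 76.5% to 92.0% of the mitochondrial reads, and without them, a choice made after the data were seen, mitochondrial genes held 0.00131% ± 0.000167 of shoot reads and 0.00376% ± 0.000696 of root reads (exact permutation p = 0.0286). Since polyadenylated RNA was selected, these organelle shares describe the reads left after that selection and do not measure organelle expression.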

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

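The single values set apart by Dixon's test were found by a rule fixed beforehand, and the test of a shoot share was chosen after its result was seen. Of 115 groups of 4 library values of the named genes and of 6 measures of whole libraries, 10, all of named genes, had a value farther from the other 3 than Dixon's 95% limit, where chance gives 5.75, but CER4 in shoot and SEP3 in root, with 0 in 3 libraries, pass this limit by construction. In root library 4, JAL10 stood at 209.5 FPKM (143 to 152 in the other root libraries), TIP1;2 at 1372 (891 to 911), PHB at 12.2 (15.5 to 16.2) and REV at 9.14 (12.9 to 13.5). In root library 1, GC1 stood at 1.26 FPKM (0 to 0.110 in the others), GBSS1 at 1.17 (0.360 to 0.461) and SEP3 at 0.453 (0 in the others). In shoot library 4, ELF4 stood at 2.38 FPKM (1.05 to 1.14) and CER4 at 0.123 (0 in the others). In shoot library 2, PHT1;1 stood at 0.932 FPKM (2.06 to 2.13 in the others).

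Photosynthesis genes differed between root libraries, with 60 of the 65 tested higher in both of root libraries 1 and 2 than in both of 3 and 4. A difference in scaling or depth is argued against by the median log2 ratio of root library 1 to 3, which was -0.00780 over all tested genes and 1.35 over the photosynthesis genes. A single share of RNA or reads from the sampled shoots as the whole cause is argued against by abundant shoot genes. For 15 of the 1119 at 100 FPKM or more in shoot, the upper 95% counting limit in root library 1 lay under 0.5 times the median share of the photosynthesis genes (20 in root library 2). For 11 it lay under 0.5 times the rise of the photosynthesis genes over root libraries 3 and 4 (0.480% of shoot). Among these 11 were AT1G23130 (617 FPKM in shoot, limit 0.0453% of it), AT3G05730 (344, 0.0744%) and TGG2 (148, 0.0810%). LHCB1.1, LHCB1.2 and LHCB1.4 were among them too, but they are photosynthesis genes themselves, and how reads were split between such near-identical copies is uncertain. The bound first written, 5% or less of the 1119 genes, would have let a single shoot share stand at 1.34%. It was changed because only 122 of the 1119 lay under the share in the mean of root libraries 3 and 4, so most could not fall under the limit. GC1, SEP3, CYP79F1 (0.606 FPKM) and TGG1 (1.89) were highest in root library 1, as a share of shoot RNA would give, so a share beside other causes, green tissue of another makeup, such as hypocotyl, and expression by the roots themselves stay open, and no biological explanation was tested.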

How the results depend on the processing

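The settings chosen only after the data were seen were the pseudocounts, the fits without root libraries 1 and 2, the filter applied again after leaving out a library, the organelle shares without rRNA, and the families except with an estimated correlation. Over the other scalings, tests, filters, block, pseudocounts and left-out libraries on the same genes, 13213 to 16139 genes changed, 13213 to 13909 without 1 library, and 7220 to 9428 changed at least 2-fold. Of the 7920 genes called at least 2-fold, 7030 to 7916 kept that call under these settings (6371 with 1 library left out and the filter applied again), and 0 changed sign, but with library totals alone 164 of all 14130 changed genes were called in the other direction. Tested against a 2-fold change, 5901 genes passed. Library totals alone moved the median log2 fold change of all genes from 0.07 to 0.58 and gave 12142 genes higher in root and 3997 in shoot (75.2% higher in root against 54.0%), and 6648 at least 2-fold higher in root (70.5% against 53.7%). That scaling reversed TIP1;2 to 0.41, ended the call of the aquaporins (1.96, adjusted p = 0.0649) and called AUX1 (0.61). The scaled library sizes were 0.770 to 0.865 times the read totals in shoot and 1.18 to 1.25 times in root. Using totals instead therefore moves genes towards root by construction, by about the same amount for TIP1;2 (from -0.14) and AUX1 (from 0.06). Which scaling is closer to the truth was not tested. With an estimated correlation, 0 lists and 0 families passed, and these lists lost their call with unchanged medians: light harvesting -7.58, Calvin cycle -7.64, chlorophyll -4.36, stomata -3.4, wax and cutin -2.88, leaf patterning -1.36, root hair 4.48, Casparian strip 4.13, root meristem 2.1, phosphate, sulfate and potassium 1.59, metal and boron 3.86, aquaporins 1.4, secondary wall 1.79, starch -2.59 and cell division 0.75. By fry, nitrate and ammonium (0.63, adjusted p = 0.00190), hypoxia (0.0651, adjusted p = 0.0136), clock (-0.66, adjusted p = 0.0136) and flower and seed markers (-2.73, 8.25e-06) passed in 1 direction. In either direction so did glucosinolate (0.48, 3.14e-07) and flavonoid (-0.44, 4.96e-09). As fry does not compare a list with the other genes, most of which changed, these passes do not set the lists apart. Hypoxia passed with 4 called genes higher in root and 4 in shoot. Without 1 library the root meristem list ranged from 0.33 to 2.29 and the families from 6 to 12, the low values from root libraries left out with the filter applied again, which by construction drops genes found in root alone (18816 to 18832 genes tested). With 2 CPM and under 0.05 CPM as limits, 299 genes were detected in root alone and 57 in shoot alone, against 600 and 121. With the replicate block 14104 genes changed against 14130, and no list's call changed, but the samples were taken to share only a number, as the labels give no pairing and same-numbered libraries had correlations of deviations of 0.0152 to 0.0710. As a hint from the data, 3 of the 4 root libraries correlated best with their own number, and root library 2 with shoot library 1 (0.0263). Of 972 values of the 54 named genes, 969 kept their side of the threshold and, where called, their direction, and besides TIP1;2 and AUX1 only PHB's call changed, lost without root libraries 1 and 2 (0.31, adjusted p = 0.0929). Uncalled, AUX1 was at -0.02 without shoot library 1 and TIP1;2 at 0.01 without root libraries 1 and 2. The planned fits by negative binomial models were not run, since they were kept for tables of counts, although whole reads were recovered. In simulated data, where only 200 genes were changed, 62 of 100 changed 2-fold were recovered.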

Other observations

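The gene groups in this paragraph and the next, the look at balanced splits, and the tests of overlaps and of the clock, except that on reviewed descriptions, were chosen after the data were seen. Forms of ferredoxin and its reductase differed in level between the tissues, except RFNR1. FD2 and FD1, leaf ferredoxin genes, stood at 2618 ± 728 FPKM in shoot and 41.3 ± 3.9 in root (log2 fold change -5.93, SE 0.19) and at 652 ± 184 and 22.4 ± 2.52 FPKM (-4.8, SE 0.18), while FD3 stood at 46.1 ± 4.25 and 196 ± 36 FPKM (2.06, SE 0.13). LFNR2, a leaf ferredoxin-NADP reductase gene, stood at 319 ± 77.2 FPKM in shoot and 2.02 ± 1.02 in root (-7.05, SE 0.28) and RFNR2, a root form, at 13.3 ± 1.66 and 87.3 ± 18.5 FPKM (2.66, SE 0.15). RFNR1 did not pass (-0.29, limma adjusted p = 0.0599). It had 2053 reads over the shoot libraries and 2547 over the root libraries, so its direction depends on the scaling. Among genes of nitrogen assimilation, nitrate reductase NIA1 (837 ± 57.5 and 10.9 ± 2.51 FPKM in shoot and root, -6.22, SE 0.14), glutamine synthetase GLN2 (1527 ± 189 and 58.9 ± 5.0 FPKM, -4.68, SE 0.11) and glutamate synthase GLU1 (408 ± 65.3 and 1.68 ± 1.55 FPKM, -7.82, SE 0.41) were higher in shoot. NIA2 (-4.47), NIR1 (-2.02) and the glutamate synthase gene GLT1 (-0.79, limma adjusted p = 0.00619) were also higher in shoot. GLT1 had 46670 reads over the shoot libraries and 42646 over the root libraries. With library totals alone the median log2 fold change of all genes moved from 0.07 to 0.58, so a change as small as that of GLT1 depends on the scaling. GLU1 was at 3.75 and 1.98 FPKM in root libraries 1 and 2 and at 0.474 and 0.510 in 3 and 4. Of these nitrogen genes, only the cytosolic glutamine synthetase gene GLN1;1 was higher in root (81.4 ± 24.5 and 174 ± 21.5 FPKM, 1.13, SE 0.19).

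Myrosinase genes, whose products cleave glucosinolates, divided by tissue. TGG1 stood at 964 ± 104 FPKM in shoot and 0.518 ± 0.92 in root (-10.23, SE 0.42), with 1.89 FPKM in root library 1 and at most 0.178 in the other root libraries. TGG2 had 148 ± 30.8 FPKM in shoot and 1 read in root, a ratio of 15708 with a 95% counting interval of 2819 to 620434. TGG4 and TGG5 had 0 shoot reads and 58.2 ± 8.34 and 57.5 ± 8.15 FPKM in root (at least 1198-fold and at least 1241-fold higher). PYK10, a beta-glucosidase gene of ER bodies, stood at 614 ± 129.7 FPKM in shoot and 5618 ± 623 in root (3.21, SE 0.18), and NAI2, needed to form ER bodies, at 84.4 ± 14.7 and 667 ± 124 FPKM (2.97, SE 0.15). BGLU22 stood at 1.15 ± 1.0 and 414 ± 94.8 FPKM (8.21, SE 0.45), and sharing of reads between the related genes BGLU21, BGLU22 and PYK10 was not tested. Of the thalianol genes, THAS1 stood at 0.233 ± 0.158 and 94.5 ± 29 FPKM (6.99, SE 0.23) and THAD at 0.227 ± 0.178 and 149.9 ± 48.4 FPKM (7.66, SE 0.27). Of the marneral genes, MRN1 and CYP71A16 had 0 shoot reads and 2.39 ± 0.878 and 12.7 ± 5.93 FPKM in root (at least 74.4-fold and at least 273-fold higher).

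Other splits of the 8 libraries into 4 and 4 were tested in the same way, with 35 splits in all. The real split gave 14130 changed genes and 7920 changed at least 2-fold, and limma called 0 genes in each of the other splits (27 to 1244 at an unadjusted p under 0.05). So 1 of 35 splits gave as many of either, the smallest share possible, which argues against chance for both counts. Each other split mixes the tissues within a group, which adds their difference to the spread, so the 0 there is no measure of false calls. For the 15 gene lists, 4 of 35 splits gave as many, the highest other count being 15, and this share does not exclude chance. It does not argue for chance either, since the 16 splits with 3 libraries of 1 tissue in each group keep part of the real difference and gave 12 to 15 lists, while the 18 splits with 2 libraries of each tissue in each group gave 0 to 3. For the 10 domain families, 14 of 35 splits gave as many, 10 of them among those 18, and the highest other split (shoot libraries 1 and 3 with root libraries 1 and 2) gave 37, so chance is not excluded.

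Some genes of active pathways were listed near 0, among them LHCB1.5 (0 reads in all 8 libraries), F3H (0 reads) and AMT1;1 (0 reads in shoot and 5 in root), whose exons lie to 100%, 93.8% and 98.4% within other annotated genes. Among protein-coding genes, 355 of 368 that were fully covered by other genes were at 0 reads (96.5%, exact 95% interval 94.0 to 98.1), against 16.3% of 19801 uncovered genes (15.8 to 16.8), a ratio of 5.93, which is consistent with reads that overlap more than 1 gene being left out of the authors' counts. This held on either strand (330 of 338 genes covered from the opposite strand and 11 of 14 from the same strand were at 0), and the ratio was 7.60 among genes with a reviewed protein description, which argues against covered genes being mostly uncharacterised ones with little expression. PGLP1 (18 reads in shoot and 0 in root) and NRT2.2 (0 reads) were not covered, so reads shared with near-identical copies stay open for them. No biological explanation was tested.

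Clock genes moved together in shoot and root libraries of the same number. The mean correlation of their deviations from the tissue means was 0.479, the highest of the 24 ways to match the libraries (1 of 24, so p = 0.0417 is the smallest possible, highest other 0.438), which is consistent with a shared time of harvest as a hypothesis. A difference that acts on all genes as the whole cause is argued against by the same-number correlations over all genes, at most 0.0710, but their mean of 0.0446 was also the highest of the 24 (highest other 0.0384), so a weak one stays open. The root hair list also ranked 1 of 24 (0.334), so 2 of the 20 lists tested did, and the hypothesis is not set apart from chance among lists.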
